A study of Arabidopsis thaliana with 4 samples.

How the data were processed

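Gene expression was measured by RNA sequencing in 4 libraries of Arabidopsis thaliana seedlings, 2 kept in air and 2 given ethylene. All came from a double mutant of the sirtuin genes SRT1 and SRT2 in the Col background, per the labels. The deposited table's own title names SRT1 alone; the labels were followed, and the table does not settle which is right. Per the labels, the seedlings were grown in the dark for 3 days at 24 °C and then held for 4 hours in hydrocarbon-free air or in the same air with 10 ppm ethylene. Total RNA was taken from seedlings with Trizol, and libraries were made with an NEB kit, per the labels' protocols. The labels do not say whether the libraries of a group came from separate batches of plants. Any spread between libraries that the authors' own test could draw on may therefore be technical. P-values of the other tests below compare genes or entries and measure no spread between libraries.

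The authors deposited a single gene-level table comparing ethylene with air. Its columns are those of Cuffdiff, a program that estimates transcript levels and tests them between conditions. The submitters' processing notes name TopHat2 version 2.0.9 and Cuffdiff version 2.2.1, with the TAIR10 build. Parameters, the annotation, the strand setting and the normalisation method are not given in the sources used here. The authors' values are in FPKM (fragments per kilobase of transcript, scaled by the number of mapped fragments), with 1 pooled value per condition, per the file headers. Values of the separate libraries were not used here, so no standard deviation, replicate plot or test across libraries could be made. Fragment totals per library are unknown. A search of low FPKM values for whole-fragment steps did not give whole fragments, so depth was not recovered, and no interval that needs depth is given.

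The deposited p-value and q-value columns hold the authors' Cuffdiff test of each gene. The q column equals Benjamini-Hochberg adjustment over the 21076 tested entries to within 5.25e-07, checked by recomputing it. The smallest deposited p was 5e-05, shared by 1200 tested entries, so entries at that limit cannot be ranked by p. The authors' log2 fold column and test statistic column are also in the table. In the deposited log2 fold column, 1357 cells had been turned into text, as had 331 cells of the deposited test statistic. Folds were therefore recomputed from the FPKM values. The deposited statistic and p do not follow a standard normal curve: the normal quantile of p was a median of 1.43 times the statistic over 17826 entries, with a 10th to 90th percentile range of 1.36 to 1.46. The square root of 2 is 1.41. Which of the 2 columns is on the intended scale could not be settled from the table. For the total count and the gene lists, calls with a standard normal reference for the statistic are therefore given beside the deposited calls where they differ by much. Gene families were not recounted in this way. Standard errors of log2 ratios printed here were obtained as the ratio divided by the deposited statistic, the wider of both readings.

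An entry of the table can name a gene, several genes or none. Of 33538 entries, 21076 were tested, 12458 had too few reads to be tested, 2 were marked low data and 2 failed. There were 776 entries naming several genes and 487 loci named in several entries. For such a locus an entry naming it alone was preferred, then a tested entry, then the entry with the highest mean FPKM. The 324 entries naming no gene held 24.0% of summed FPKM in air and 22.8% in ethylene. They were left out of the main count, which covers the 20786 tested entries that name a gene. Both of these choices were made after the table was seen. Gene symbols, products, gene lengths and coordinates come from the TAIR10.1 annotation of NCBI, which held 32674 of the 33414 loci named. Columns of per-sample values left unused numbered 0.

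A gene is called here when the authors' deposited table gives it a q of 0.05 or less. The size of a change is log2((ethylene FPKM + 1)/(air FPKM + 1)), which understates the change of low genes. Plain folds are ratios of the deposited FPKM values. No fold is given against a value listed at 0, but counts at a minimum fold keep all calls listed at 0 in 1 condition. For 29 gene lists, and for organelle-encoded and ribosomal protein genes, the called members were counted. Members called after Benjamini-Hochberg adjustment of the deposited p over the list alone were counted too. The list's median change was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile under 2.5 or over 97.5 is treated as standing apart. It describes these libraries and is not a p-value. Because the annotation does not pair their symbol with their locus, 10 list members were dropped. Genes named in the text are 103 chosen by rule. They are SRT1, SRT2 and the locus listed beforehand as ENAP1. The 10 largest rises and the 10 largest falls among called genes of at least 1 FPKM in either condition were added. From each list came up to 4 called members with the largest change, or at most 2 members of a list with no call. Of the genes this rule gives, 1 is not reported here. Any other gene named was chosen after its values were seen. Groups, lists, the naming rule and most alternatives were fixed before the data were examined.

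The list percentile was tested on simulated data, with 200 lists of 15 members at each fold. Members were drawn from entries with a mean of at least 5 FPKM, against a background of 33214 entries. Changes were first shuffled among entries of like expression, and the same fold was then added to the log2 change of every member. Fewer random lists were drawn than for the real lists. The percentile stood apart in 4.5% of unchanged lists, 97.5% of lists changed 1.25-fold and 100% of lists changed 1.5-fold or 2-fold. Shorter lists and lists of lower genes were not simulated, so how often a change would be seen in those is unknown. Simulated members did not vary together as members of a real list can. How often an unchanged real list would stand apart is therefore unknown too. Alternatives were a q of 0.01, minimum folds of 1.5 and 2, minimum levels of 1 and 5 FPKM, Bonferroni adjustment, unadjusted p, pseudocounts of 0.1 and 5, and centring on the median change. Leaving out a library and a replicate block need values per library and were not run. Added after the data were seen were the standard normal reference, counts with unnamed entries, with entries of 1 gene only and with entries above 0 in both conditions, the comparison of gene families and the comparison of neighbouring genes. Families are entries of 1 gene whose product names are the same after text behind a comma and trailing numbers or short codes are removed, with at least 10 members. Such a name can join unlike genes, as "cytochrome" does. They were compared with 10000 random sets matched on expression. Sequence matches between neighbouring genes were found with tblastx of BLAST 2.17.0 at an E-value limit of 1e-05. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.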

Results

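Transcript levels were compared between ethylene and air in etiolated (dark-grown) seedlings of the srt1srt2 double mutant. SRT1 and SRT2 encode sirtuins, histone deacetylases that depend on NAD. Ethylene is a gaseous plant hormone that shortens and thickens the dark-grown seedling and exaggerates its apical hook. Each condition had 2 libraries, pooled by the authors into 1 FPKM value per gene, and the depth of the libraries is unknown. The series title concerns the part of SRT2 and of its partner ENAP1 in repression by ethylene. The comparison made here asks which transcripts respond to 4 hours of ethylene when both sirtuin genes are mutated. No wild-type libraries were analysed here, so whether any response differed from that of the wild type was not tested.

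The mutated genes were low in both conditions. SRT1 (AT5G55760, TAIR10.1 chromosome 5, 22567222 to 22571008) was at 3.88 FPKM in air and 3.23 in ethylene. SRT2 (AT5G09230, chromosome 5, 2871365 to 2873789) was at 1.92 FPKM in air and 2.09 in ethylene. Without wild-type libraries these levels do not check the genotype, since an insertion can leave part of a transcript. The locus listed beforehand as ENAP1 (AT3G11100) was at 43.3 FPKM in air and 41.3 in ethylene. The annotation gives that locus no such symbol and describes it as a sequence-specific DNA-binding transcription factor. None of these 3 genes was called in the authors' deposited table, where Cuffdiff with Benjamini-Hochberg adjustment gave q values of 0.735, 0.937 and 0.897 in that order.

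Ethylene changed 2347 of the 20786 tested entries that name a gene, with 995 higher and 1352 lower than in air. Lower entries thus made up 57.6% of the calls. Most listed ethylene-induced and root hair genes rose, 15 of 18 and 9 of 13. Auxin-response genes fell in 12 of 30, light-harvesting and photosynthesis genes in 8 of 18, and abscisic acid and cold genes in 6 of 15. At least a 2-fold change was seen in 1090 of the called entries, 510 higher and 580 lower. These include all 60 calls listed at 0 in 1 condition, 36 higher and 24 lower, for which no fold can be given. The median size of a called change was 0.90 on the log2 scale among higher entries and 0.85 among lower ones. Protein-coding genes made up 2305 of the calls. The count rests on the deposited p. With a standard normal reference for the deposited statistic, 1201 entries were called, 535 higher and 666 lower. That reading was tried after the data were seen. Under it 13 of the listed ethylene-induced and 6 of the root hair genes were higher. Lower were 8 auxin-response, 2 light-harvesting and photosynthesis and 6 abscisic acid and cold genes. The median log2 change of the 19700 tested entries at 1 FPKM or more in either condition was 0.0092.

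**Figure D1:**
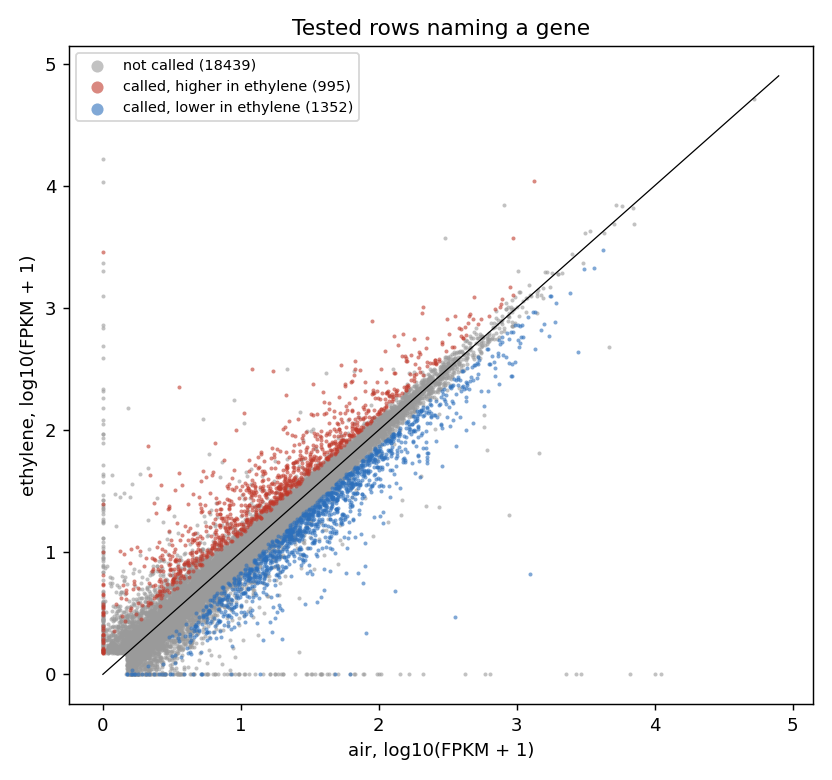
Level of each tested entry that names a gene in air (horizontal) and in ethylene (vertical), both as log10(FPKM + 1), with the line of equal levels. Red points are the 995 entries called higher in ethylene, blue points the 1352 called lower and grey points those not called, in the authors' deposited table.

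The largest rises joined genes of several kinds. AT1G62680 (chromosome 1, 23207017 to 23209987), which encodes a pentatricopeptide repeat protein of the kind that acts on organelle RNA, went from 2.57 to 225 FPKM, an 87.6-fold rise. Its log2 ratio was 6.45 with a standard error of 0.42. ORS1 (AT2G41230), annotated as an organ-size protein, rose 63.6-fold from 1.14 to 72.4 FPKM. It shares its span in the table with AT2G41231, which was at 0.533 and 150.2 FPKM and was not called, so reads of that pair may not be separable. AZI1 (AT4G12470), a lipid-transfer-like protein with a part in systemic defence, rose 28.3-fold to 313 FPKM. The peroxidase AT1G49570 rose 34.9-fold, the acyltransferase AT2G39980 18.8-fold to 306 FPKM, the cytochrome P450 gene CYP718 20.8-fold and the glyoxal oxidase-related AT1G19900 14.3-fold. The pentatricopeptide repeat entry AT2G41080/AT2G41082 rose 16.9-fold. AT1G08005 was listed at 0 in air and 24.0 FPKM in ethylene. The entry AT2G01020, annotated as 5S ribosomal RNA, was listed at 0 in air and 2856 FPKM in ethylene. Its position puts that annotation in doubt, and its rise is taken up below with the other ribosomal RNA entries.

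Among the largest falls, small RNA genes held 4 of the 10 places. The snoRNA entry AT1G75163/AT1G75166 fell from 1253 to 5.61 FPKM, the snoRNA AT3G27865 from 355 to 1.96 and the snoRNA AT3G21805 from 130 to 3.85. The precursor of the microRNA MIR396a fell from 61.1 FPKM to a value listed at 0. Of the 24 tested snoRNA entries 4 were called, all lower, but 14 of the 24 had a higher value in ethylene than in air. The median log2 change of the 24 was 0.22. Wide differences in both directions also went uncalled. AT2G05765 was at 303 FPKM in air and 3705 in ethylene, and AT3G47342/AT3G47347/AT3G47348 at 1440 and 63.8. The named snoRNA falls are therefore to be read with caution. SDR1 (AT3G61220, chromosome 3, 22662849 to 22664493), which encodes a short-chain reductase of the Rossmann-fold type, fell 68.1-fold from 79.5 to 1.17 FPKM. Its log2 ratio was -6.09 with a standard error of 0.89. AT1G75900 and AT1G29660, both GDSL-type lipases, fell 16.5-fold and 11.9-fold. The copper transport family gene AT3G20180 fell 11.7-fold, from 78.2 to 6.66 FPKM. The short uncharacterised genes AT1G52857 and AT5G50361 fell from 47.2 and 12.9 FPKM to values listed at 0.

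Most genes listed as induced by ethylene rose. Of 18 members of this list, 15 were called higher and none lower, and 16 were called higher when adjusted over the list alone. ERF1 (AT3G23240, chromosome 3, 8295617 to 8296604), a transcription factor directly activated by EIN3, was listed at 0 in air and 9.07 FPKM in ethylene. ARGOS, a regulator of organ size and ethylene sensitivity, rose 5.36-fold to 205 FPKM. EDF3, an AP2 and B3 domain transcription factor, rose 5.34-fold. The list median was 1.57 on the log2 scale, higher than in all 10000 random lists. With the normal reference for the statistic, 13 members were called higher; ERF1 has no numeric statistic and could not be among them.

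Part of the receptors and the signalling chain rose. Among 18 members, 7 rose and none fell, and adjusted over the list alone 8 rose and 1 fell. The receptor gene ETR2 (AT3G23150, chromosome 3, 8254559 to 8257888) rose 5.78-fold, from 7.90 to 45.7 FPKM, with a log2 ratio of 2.53 and a standard error of 0.25. RTE1, which acts with the receptor ETR1, rose 3.89-fold, the receptor ERS2 3.13-fold and the kinase CTR1 3.00-fold from 25.5 to 76.4 FPKM. The list median of 0.21 lay at percentile 99.3, and 6 of the 7 genes that rose, all but EIN2, also stand in the list of known ethylene-induced genes. The normal reference gave 7 higher calls.

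Some genes of ethylene synthesis rose. ACO4 (AT1G05010, chromosome 1, 1431177 to 1433010) went from 88.6 to 774 FPKM, an 8.74-fold rise with a log2 ratio of 3.13 and a standard error of 0.21. ACO5 rose 3.64-fold and ACO1 3.59-fold. These genes encode ACC oxidases. A further tested entry of ACO1 in the same span was at 0.814 FPKM in air and 0.346 in ethylene and was not called. Of the 15 genes of ethylene biosynthesis, 4 were higher and 1 lower, and adjusted over the list alone 4 were higher and 4 lower. The gene that fell was ACS6, an ACC synthase named here after its values were seen, at 15.3 FPKM in air and 8.51 in ethylene. With the normal reference 4 were higher and 0 lower, so its call was lost. The list's median change was -0.03, at percentile 26.2.

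In the ethylene response factor family, 8 of 26 members rose and none fell. Adjusted over the list alone, 8 rose and 1 fell. Besides ERF1, ERF2 rose 20.2-fold from 0.426 FPKM with a standard error of 1.13 on the log2 scale, ERF11, a repressor, 10.8-fold from 0.856 to 9.28 FPKM, and RAP2.3 4.79-fold from 65.9 to 316. The list median of 0.25 lay at percentile 99.97. The normal reference gave 7 higher calls, since ERF1 has no numeric statistic.

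**Figure D2:**
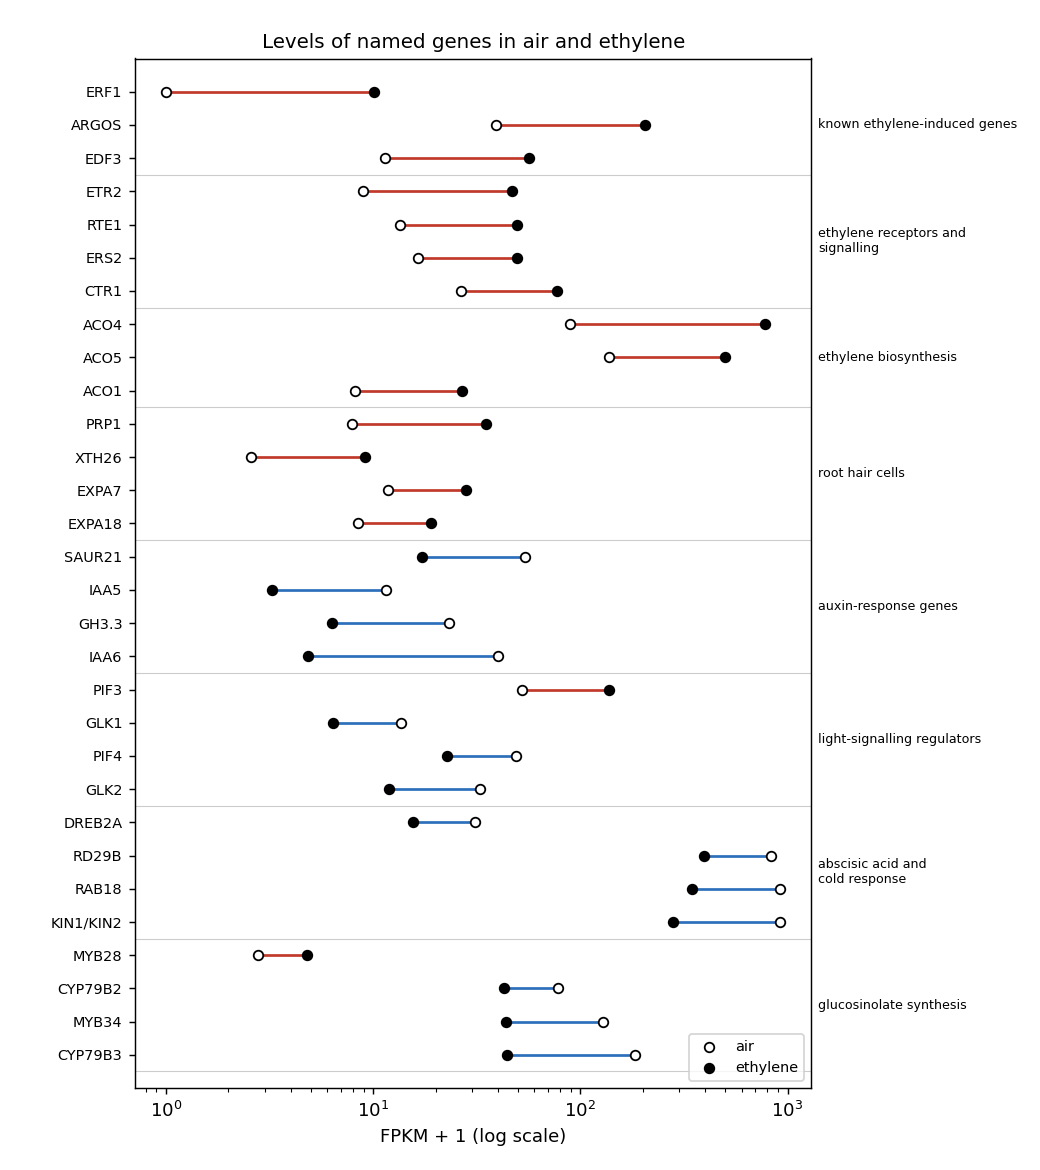
FPKM + 1 on a log axis for named genes of 8 lists in air (open circles) and ethylene (filled circles), each the authors' pooled value, with a red line for a rise and a blue line for a fall. Ethylene pathway and root hair genes move to the right, for example ACO4 from 88.6 to 774 FPKM, and most auxin-response, abscisic acid and glucosinolate genes move to the left, for example IAA6 from 39.1 to 3.86 FPKM.

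Part of the auxin-response genes fell. Of 30 members, 12 were lower and 3 higher, and adjusted over the list alone 15 were lower and 3 higher. IAA6 (AT1G52830, chromosome 1, 19672476 to 19673652), a repressor of auxin signalling, fell 10.1-fold from 39.1 to 3.86 FPKM, with a log2 ratio of -3.34 and a standard error of 0.50. GH3.3, an auxin-conjugating enzyme, fell 4.17-fold, IAA5 4.71-fold and SAUR21 3.28-fold. The call of IAA5 was lost with the normal reference. SAUR21 has close copies, and how the authors' counting split reads among them is not given, so its value is uncertain. Those that rose, named after their values were seen, were IAA20 (1.85-fold), GH3.2 (1.57-fold) and IAA4 (1.37-fold). The list median of -0.60 was lower than in all random lists. With the normal reference 8 were lower and 1 higher.

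Auxin synthesis and transport moved both ways, with 2 of 22 members higher and 5 lower, or 4 higher and 6 lower when adjusted over the list alone. YUC9, an auxin synthesis enzyme, rose 5.10-fold from 0.806 to 4.11 FPKM, and TAR2 rose 2.48-fold. LAX2, an auxin importer, fell 2.18-fold, and YUC8 fell 2.07-fold. Its median change was 0.05, at percentile 76.9. Under the normal reference 1 was higher and 3 lower, and TAR2 was no longer called.

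Genes of cell wall loosening split into 2 groups. Among 23 expansins and xyloglucan endotransglucosylases, 11 rose and 6 fell, and adjusted over the list alone 11 rose and 9 fell. XTH13 rose 5.20-fold, XTH26 5.11-fold and XTH12 3.57-fold, from levels of 2.94, 1.59 and 6.06 FPKM in air. EXPA5, an expansin of growing organs, fell 5.34-fold from 47.4 to 8.87 FPKM. The list median was 0.35, at percentile 100. Normal-reference calls were 10 higher and 4 lower. Cellulose synthesis changed little: of 10 members only CESA2 was called, at 38.2 FPKM in air and 53.7 in ethylene, and 1 adjusted over the list alone. That call was lost with the normal reference. The list median was 0.01, at percentile 51.2.

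Most root hair genes listed rose. Of 13 markers of root hair cells, 9 were higher and none lower, and 10 were higher when adjusted over the list alone. PRP1, a cell wall protein of root hairs, rose 4.93-fold from 6.90 to 34.0 FPKM. EXPA7 rose 2.52-fold and EXPA18 2.40-fold, and XTH26 (5.11-fold) is also in this list. The median of 0.77 was higher than in all random lists, and 6 genes were higher under the normal reference. Markers of stomatal and xylem cells gave no calls in the authors' Cuffdiff test, but matched random lists gave under 1 call in each direction on average. These held 0.076 higher and 0.065 lower calls for the stomatal list, whose median mean level was 1.11 FPKM. For the xylem list they held 0.355 and 0.479. The absence of calls therefore tells little about either cell type. Stomatal lineage genes numbered 6, with 0 called, 0 adjusted over the list alone, 0 at an unadjusted p of 0.05, and a median of -0.0059 at percentile 49.7. In that list TMM was at 2.76 FPKM in air and 0.449 in ethylene, and EPF2 at 0.385 and 1.26. The 6 xylem genes had 0 calls, 0 adjusted over the list alone, 0 at an unadjusted p of 0.05, and a median of 0.01 at percentile 51.4. XCP2 was at 157 FPKM in air and 188 in ethylene, and XCP1 at 86.8 and 103.

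**Figure D3:**
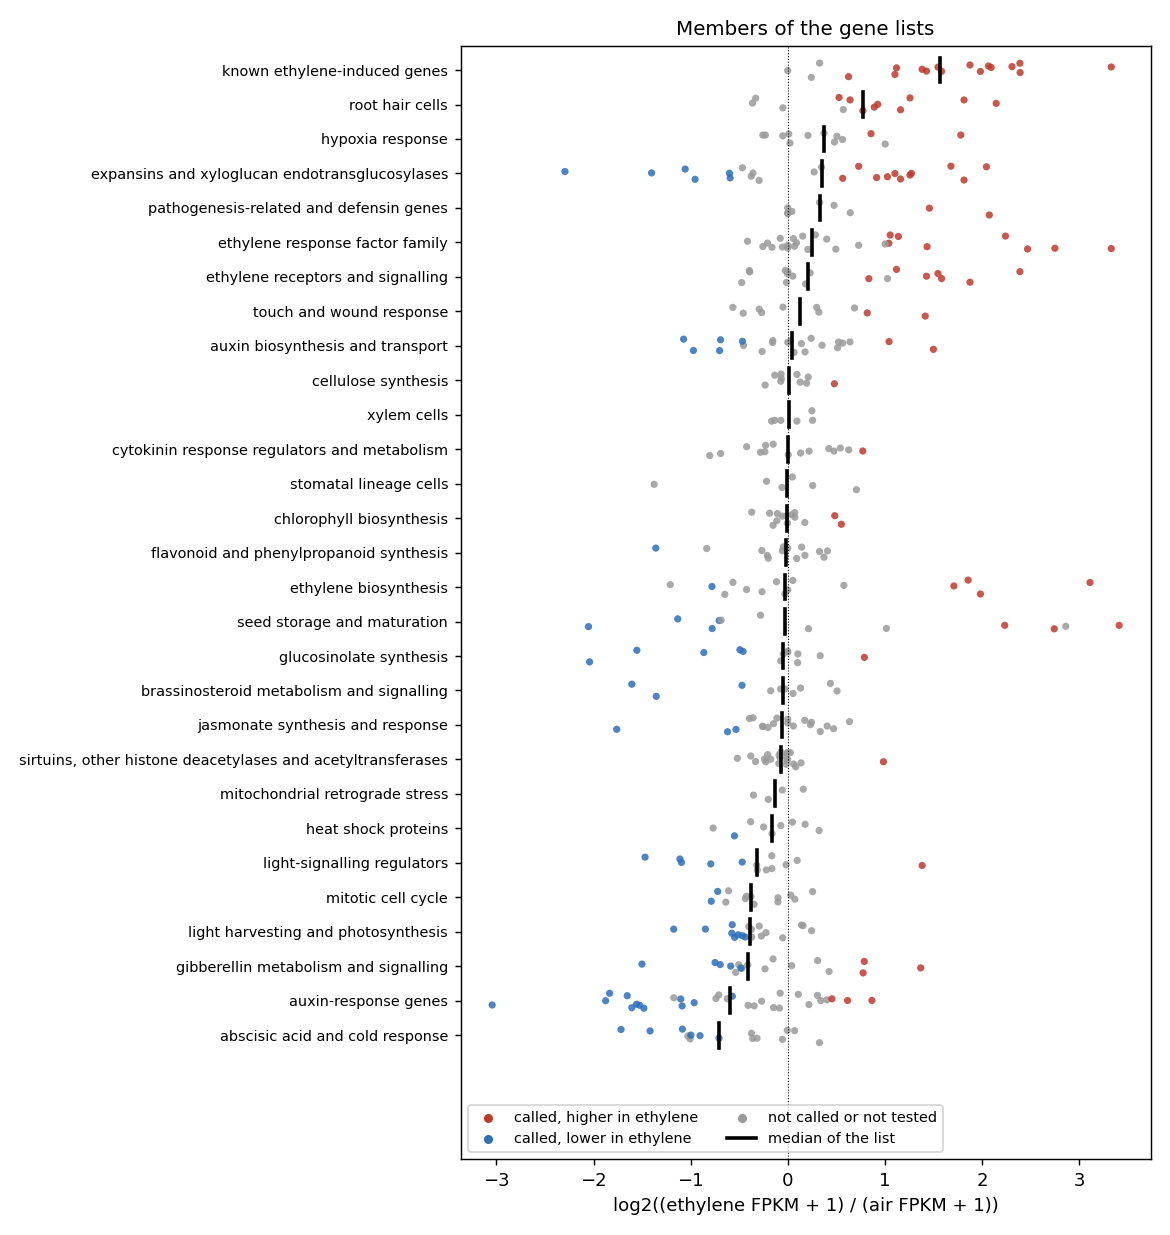
Change of each member of the 29 gene lists, as log2((ethylene FPKM + 1)/(air FPKM + 1)), with red points for members called higher, blue for members called lower, grey for the rest and a black bar at each list's median. Medians run from -0.71 for abscisic acid and cold response to 1.57 for known ethylene-induced genes.

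Part of the light-harvesting and photosynthesis genes fell. Of 18 entries covering 20 genes, 8 were lower and none higher, or 11 lower when adjusted over the list alone. LHCB2.3 fell 2.28-fold from 132 to 57.8 FPKM and LHCA1 1.80-fold from 455 to 252 FPKM. The shared entry of LHCB1.1 and LHCB1.2 fell 1.49-fold, as did LHCB2.1. The RBCS entries, named after their values were seen, were not called, with log2 changes of 0.14 for RBCS1A, 0.16 for RBCS1B/RBCS2B and 0.25 for RBCS3B. The list median was -0.39, at percentile 0.07. With the normal reference 2 were lower, and neither the shared entry of LHCB1.1 and LHCB1.2 nor LHCB2.1 was called. Among 13 regulators of light signalling, 5 were lower and 1 higher, the same numbers when adjusted over the list alone. GLK2 and GLK1, activators of photosynthesis genes, fell 2.93-fold and 2.34-fold, and PIF4, a growth-promoting factor, fell 2.21-fold. PIF3, which ethylene is known to induce, rose 2.64-fold from 51.6 to 136 FPKM. This list's median was -0.31, at percentile 0.26, with 4 lower and 1 higher under the normal reference.

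Chlorophyll biosynthesis changed in 2 of 14 members, both higher, and 2 adjusted over the list alone. PORA and PORB, which reduce protochlorophyllide in the light, rose 1.47-fold and 1.40-fold to 583 and 981 FPKM. Neither call held with the normal reference. The median of -0.0087 lay at percentile 36.2.

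Part of the abscisic acid and cold response genes fell. Of 15 entries covering 16 genes, 6 were lower and none higher, and adjusted over the list alone 8 were lower and 1 higher. The shared entry of KIN1 and KIN2 fell 3.29-fold from 917 to 278 FPKM. RAB18, a dehydrin, fell 2.68-fold from 924 to 345 FPKM, RD29B from 833 to 393 and DREB2A 2.06-fold. The list median of -0.71 was lower than in all random lists, and the normal reference also gave 6 lower calls.

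Seed storage and maturation genes moved apart. Of 12 members, 3 were higher and 4 lower, and adjusted over the list alone 4 were higher and 5 lower. Of the 4 genes for 2S albumins, 3 rose from low levels, SESA3 17.8-fold to 24.1 FPKM, SESA1 16.3-fold to 9.67 and SESA2 7.09-fold. SESA4, named after its values were seen, was at 0.064 FPKM in air and 6.74 in ethylene and was not called. EM1, a late embryogenesis protein, fell from 222 to 52.7 FPKM. Also lower were OLEO1, OLEO2 and EM6, named after their values were seen. The list median was -0.03, at percentile 33.2. Normal-reference calls were 3 higher and 3 lower.

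Other hormone lists changed in part. Among 17 gibberellin genes, 3 were higher and 5 lower, or 4 higher and 7 lower when adjusted over the list alone. RGL3, a DELLA repressor, fell 3.24-fold, while GA2OX8 and GA2OX6, which inactivate gibberellin, rose from 1.73 to 6.05 FPKM and from 11.9 to 21.1 FPKM, and the receptor GID1C rose 1.76-fold. The median was -0.41, at percentile 0.01. The normal reference gave 1 higher and 1 lower, and neither GA2OX gene was called. Of 10 brassinosteroid genes, 3 were lower, and adjusted over the list alone 2 were higher and 3 lower. The synthesis genes DWF4, BR6OX1 and CPD fell 3.21-fold, 3.15-fold and 1.39-fold, the last not called with the normal reference. That list's median was -0.05, at percentile 22.8. Of 15 cytokinin genes only ARR3 was called, 1.80-fold higher and not so with the normal reference. Adjusted over the list alone 3 were higher and 3 lower, and the median was 0.0055 at percentile 50.4.

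Jasmonate genes numbered 20 entries for 21 genes, with 3 lower and none higher, and 3 lower when adjusted over the list alone. VSP2, a vegetative storage protein, fell 3.71-fold, VSP1 1.55-fold and the regulator MYC2 1.46-fold. Only 1 of these calls held with the normal reference, that of VSP2, and the median of -0.06 lay at percentile 15.6. Among 9 pathogenesis-related and defensin genes, 2 were higher, or 3 adjusted over the list alone. PDF1.1 rose 4.42-fold and PR4 2.76-fold from 147 to 406 FPKM, and the normal reference gave 2 higher calls. The median was 0.33, at percentile 99.98, although 5 of the 9 members were not tested.

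Genes of glucosinolate synthesis fell in part. Of 13 members, 6 of them not tested, 5 were lower and 1 higher, or 5 lower and 2 higher when adjusted over the list alone. CYP79B3 and CYP79B2, which convert tryptophan to indole-3-acetaldoxime, fell 4.19-fold from 182 to 43.4 FPKM and 1.84-fold. MYB34, their activator, fell 2.98-fold, and CYP83B1 and SUR1, named after their values were seen, fell 1.41-fold and 1.39-fold. MYB28, a regulator of the aliphatic branch, rose 2.14-fold, a call lost with the normal reference, under which 3 were lower. The median of -0.05 lay at percentile 8.53. It was -0.36 with a pseudocount of 0.1 and -0.49 among members of 1 FPKM or more, at percentiles 0.43 and 0.5. Among 14 flavonoid and phenylpropanoid genes only F3H was called, 3.84-fold lower, and 1 adjusted over the list alone. The median was -0.02, at percentile 39.6.

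Chromatin and stress lists held few calls in number, but matched random lists held few too. The chromatin list had 1 higher call and 0 lower, against 1.02 and 1.38 in random lists on average. Higher calls numbered 2 for hypoxia genes, against 0.49, and 2 for touch and wound genes, against 0.41. Heat shock genes had 1 lower call, against 0.39. For mitochondrial stress genes random lists held 0.15 higher and 0.23 lower calls. Among 22 entries for sirtuins, other histone deacetylases and acetyltransferases, only HDT3 was called, and 1 adjusted over the list alone. HDT3 (AT5G03740, chromosome 5, 981859 to 984289), a plant-specific histone deacetylase, rose 2.00-fold from 40.2 to 80.5 FPKM, with a standard error of 0.23 on the log2 scale. The median was -0.07, at percentile 11.9. Of 13 hypoxia genes, 2 were higher, or 3 adjusted over the list alone. HB1, a hemoglobin, rose 3.69-fold and PCO1 1.95-fold, the latter not called with the normal reference, and the median of 0.37 lay at percentile 99.9. Of 10 touch and wound genes, 2 were higher, also adjusted over the list alone. ZAT10 rose 3.03-fold, and the entry of TCH3, which also names a neighbouring gene, rose 1.78-fold. That median was 0.12, at percentile 84.3.

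Of 9 heat shock genes, HSP70 alone was lower, at 121 FPKM in air and 82.4 in ethylene, and 1 adjusted over the list alone. Its call was lost with the normal reference, and the list median was -0.16, at percentile 7.21. The 4 mitochondrial stress genes had 0 calls in the authors' Cuffdiff test, 0 adjusted over the list alone and 0 at an unadjusted p of 0.05, with a median of -0.13 at percentile 26.4. OM66 was at 2.67 FPKM in air and 1.87 in ethylene, and NDB2 at 39.2 and 34.0. Of 13 mitotic genes, 2 were lower, or 3 adjusted over the list alone. CDKB2;2 and CYCB2;2 fell 1.88-fold and 1.85-fold. Neither call held with the normal reference. The median of -0.38 lay at percentile 0.3.

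Signs of library composition were looked at beside these groups. Ribosomal protein genes stayed level, with 3 of 292 entries higher and 3 lower, 0 adjusted over the list alone, and a median of 0. Random lists of that size held 21.1 higher and 29.6 lower entries on average. All 130 chloroplast-encoded and 141 mitochondrion-encoded genes were listed at 0 in both conditions and were not tested, so the table does not report on organelle transcripts. Of the ribosomal RNA entries, AT2G01020 alone was called. Its neighbour AT2G01021, annotated as an uncharacterized protein and named after its values were seen, rose 8.21-fold from 1335 to 10958 FPKM. The 5.8S gene AT3G41979 was at 157 FPKM in air and 198 in ethylene and was not called. It starts at 14199753, next after the ribosomal RNA gene AT3G41768, which ends at 14199484. AT2G01020 starts at 5782, next after the ribosomal RNA gene AT2G01010, which ends at 5513. AT2G01020 may therefore be a 5.8S gene too, despite its annotation. AT2G01010 was also listed at 0 in air. Whether the libraries differed in ribosomal RNA content was not tested, so the rises of AT2G01020 and AT2G01021 are not read as a response to ethylene. Summed FPKM of entries annotated as ribosomal RNA was 157 in air and 4701 in ethylene, that of snRNA 38.3 and 114, and that of tRNA 9.36 and 2028. No tRNA or snRNA entry was called, and the tRNA sum in ethylene came almost wholly from AT5G60285, listed at 0 in air and 2018 FPKM in ethylene. Of all calls, 60 were entries listed at 0 in 1 condition, 36 of them higher and 24 lower in ethylene.

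Several list medians depended on the pseudocount or on the level asked of members. With a pseudocount of 5 the median was 0.09 for the ethylene response factor family, 0.11 for pathogenesis-related and defensin genes, 0.51 for root hair cells, -0.32 for auxin response, -0.37 for abscisic acid and cold response and -0.20 for gibberellin genes, each still outside the percentile limits. Among members of 1 FPKM or more it was 0.39 for the ethylene response factor family and 1.05 for pathogenesis-related and defensin genes, and with a pseudocount of 0.1 it was 0.46 for the ethylene response factor family.

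The size of the test's error was known only through the authors' statistic. Over the 88 called named genes with a finite log2 ratio, its implied standard error ran from 0.20 to 1.16 with a median of 0.30. Of the 94 called named genes, 68 stood at the smallest q of the authors' deposited table, where Cuffdiff with Benjamini-Hochberg adjustment gave 0.000878. The smallest log2 ratio in size among all calls was 0.40. Another tested entry shares its span with 15 of the named genes, IAA5, ARGOS, EM1, DREB2A, F3H and SRT2 among them, so reads of these genes and their partners are not fully separable. How many of the libraries showed each direction cannot be read from pooled values.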

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

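All tests in this part were chosen after the results were seen.

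Signal was found in 2 entries that the authors marked as low data and did not test. The 18S ribosomal RNA gene AT2G01010 was listed at 0 in air and 673 FPKM in ethylene, and the 18S gene AT3G41768 was listed at 0 in air and 975 FPKM in ethylene. No explanation is weighed here for these values.

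Of the 4 genes for 2S albumins 3 rose, while OLEO1, OLEO2, EM1 and EM6 of the same list fell. The 5 other members, SESA4, OLEO4, CRA1, CRB and CRC, were not called. One candidate explanation is more seed material in the ethylene libraries. In a first version of the test, over the other 8 members of the list, 4 were lower and none higher, with a median log2 change of -0.70, but most had levels in air that would hide a rise of the albumins' size, the largest being 22.8 FPKM. The 2 members below that level, CRB (0.767 FPKM in air, 2.57 in ethylene) and OLEO4 (6.57 and 3.71), were not called. Adjusted over the list alone, CRB was higher and OLEO4 lower. Their median log2 change of 0.16 thus lies between changes in opposite directions. Seed material therefore cannot be told apart from a change in the albumin genes. Reads shared between the 4 albumin copies through exact 50-base matches are argued against. The largest share of 50-base words of an albumin transcript held by another was 0%, while in 3 RBCS copies it was 14.0% to 20.2%. Shorter or inexact matches were not looked at, so reads shared through those were not excluded. A biological response of these genes to ethylene stays open, as untested.

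Called entries listed at 0 in 1 condition were often short. Of 83 such entries, those naming no gene included, 42.2% were shorter than 600 bases, against 1.57% of 2287 other called entries, unnamed ones also included (2-sided Fisher's exact test, p = 3.3e-35). Left out were 4 called entries whose genes have no length in the annotation. Entries naming a gene made up 60 of the 83, and most of the 27 called entries naming no gene were among the rest. Length was that of the annotated gene for named entries and that of the span in the table for unnamed ones. The groups thus differ in make-up and in how length was taken, and named entries alone were not compared. Limits of 200, 300 and 1000 bases gave 20.5%, 25.3% and 65.1%, against 0.35%, 0.39% and 9.27%. Short features being estimated from few fragments could give such a difference, and the mix of named and unnamed entries may account for part of it. Low fragment numbers themselves could not be seen. A true loss or gain of these transcripts in ethylene stays open.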

How the results depend on the processing

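Leaving out a library was not run, because the table holds 1 pooled value per condition. No paired analysis was possible because the columns carry no replicate numbers. Depth is unknown, so what it limits was not measured. The standard normal reference and the choices of entries were added after the data were seen. Of the alternatives for the number of called genes, 2347 in the main count, these moved it by over 1.5 times. At least a 2-fold change left 1090, 510 higher and 580 lower. This count and the 1.5-fold count below keep all 60 calls listed at 0 in 1 condition. Bonferroni adjustment left 0 in total, 0 higher and 0 lower, by construction, since the smallest p of 5e-05 times 21076 tests exceeds 0.05. An unadjusted p gave 4263, 1906 higher and 2357 lower. The normal reference for the statistic gave 1201, 535 higher and 666 lower; 1177 of these were among the deposited calls, 24 were not, and 60 deposited calls had no numeric statistic. The cause was not tested. The other alternatives gave 1692 (q of 0.01), 1958 (1.5-fold), 2353 (1 FPKM), 2295 (5 FPKM), 2374 (unnamed entries included), 2265 (1 gene only) and 2287 (above 0 in both), and centring changed no direction. Of 30 list medians, centring moved none across the percentile limits. Glucosinolate synthesis newly stood apart with a pseudocount of 0.1 (median -0.36) and among members of 1 FPKM or more (-0.49), as did heat shock with a pseudocount of 5 (-0.14); the cause was not tested. The medians of 20 of the 30 lists moved by over 1.5 times or changed sign under at least 1 of the pseudocounts, the minimum level or centring. All 103 named genes kept their direction under both pseudocounts and centring. Under the normal reference 79 kept their side of the threshold, 18 lost their call and 6 had no numeric statistic.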

Other observations

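All tests in this part were chosen after the data were seen. Gene families, taken as genes whose product names are the same once trailing numbers and text behind a comma are removed, were compared with random sets matched on expression. Of 272 families, 7 held more higher calls than such sets and 12 more lower calls at a Benjamini-Hochberg adjusted p of 0.05, over all 272 families in both directions. The smallest p that the random sets can give is 0.0001. Families were counted with the deposited calls only. They were not recounted with the normal reference for the statistic, so their counts and p-values rest on the deposited p.

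Peroxidases, enzymes that act in the cell wall, rose in 13 of 47 members and fell in 4, with AT5G64120 going from 52.0 to 339 FPKM and AT5G64100 from 205 to 913. Xyloglucan endotransglucosylases rose in 11 of 25 and fell in 4, XTH7 going from 20.4 to 194 FPKM. An invertase and pectin methylesterase inhibitor family rose in 7 of 20 and fell in 2. These 3 families had an adjusted p of 0.0042 for rises (random sets, n = 47, n = 25 and n = 20 members). The annotation also holds the invertase and pectin methylesterase inhibitor superfamily under a slightly different name, where 5 of 28 rose and 4 fell (random sets, n = 28, adjusted p = 0.063 for rises). The entries under both names were not tested as 1 family. The family annotated as root hair specific rose in 5 of 14 and fell in none, and AP2-type factors annotated as integrase-type DNA-binding proteins rose in 11 of 52 and fell in 3, DREB26 going from 15.6 to 58.4 FPKM. Both had an adjusted p of 0.0073 for rises (random sets, n = 14 and n = 52 members). All genes named from these families were chosen after their values were seen.

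Another 6 families held more falls than random sets. Enzymes of very long chain fatty acids, the 3-ketoacyl-CoA synthases, fell in 9 of 17 and rose in 2, with KCS9 going from 102 to 30.8 FPKM and KCS6, a wax synthesis gene, from 694 to 319. ABC-2 type transporters fell in 6 of 13 and rose in 1, and ABCG12, which exports wax, went from 143 to 66.6 FPKM. GDSL lipases fell in 16 of 44 and rose in 4. Genes annotated as the superfamily of bifunctional inhibitors, lipid-transfer proteins and 2S albumins fell in 15 of 53 and rose in 3, LTPG2 going from 208 to 70.6 FPKM. The albumin genes SESA1, SESA2 and SESA3 carry another product name and are not among the 53. Arabinogalactan proteins fell in 14 of 28 and rose in 1, AGP21 going from 1351 to 457 FPKM. Late embryogenesis abundant proteins fell in 7 of 10 and rose in none, LEA7 going from 873 to 353 FPKM. Each of these 6 families had an adjusted p of 0.0042 for falls (random sets, n = 10 to n = 53 members). A separate family, named late embryogenesis abundant hydroxyproline-rich glycoproteins, fell in 1 of 29 and rose in 2.

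SAUR genes held more calls than random sets in both directions, with 25 of 68 lower and 10 higher (random sets, n = 68, adjusted p = 0.0042 and adjusted p = 0.013). AT4G34760 went from 90.9 to 18.6 FPKM, while AT4G09530 went from 50.2 to 185. Expansins did likewise, with 9 of 21 lower and 6 higher (random sets, n = 21, adjusted p = 0.0042 and adjusted p = 0.018). Pectin lyase-like genes fell in 12 of 53 and rose in 5 (random sets, n = 53, adjusted p = 0.0042 for falls). The other families with more falls were bHLH factors, with 15 of 82 lower and 6 higher (n = 82, adjusted p = 0.01), the mixed group whose names shorten to cytochrome, with 20 of 126 lower and 12 higher (n = 126, adjusted p = 0.0042), and major facilitator proteins, with 14 of 88 lower and 6 higher (n = 88, adjusted p = 0.049). The adjusted p of the major facilitator proteins lies close to the limit of 0.05, and how many calls of any family the normal reference would keep is not known. Members of a family are not independent, and reads shared between close copies were not tested for these families.

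Neighbouring genes changed in the same direction more often than chance. Among adjacent tested genes, 332 pairs were both called, against 257 by chance, and 69.9% of these pairs changed in the same direction, against 51.2% with directions shuffled (1000 permutations, 1-sided p = 0.001, the smallest they can give). Copies of a gene family standing side by side may account for part of this, since the 89 pairs with a sequence match shared direction in 85.4%. They do not account for the 243 pairs without a match, of which 64.2% shared direction (permutation p = 0.001). In a first version that told families apart by product name it was 65.4% of 263 pairs (permutation p = 0.001). Transcripts reading past their end into the next gene are argued against for 68 of the pairs without a match. These pairs point away from each other and do not overlap, and 64.7% of them shared direction (permutation p = 0.015). A first version of that test, on 117 pairs on opposite strands without overlap, gave 64.1% (permutation p = 0.005). Pairs in other orientations were not tested apart, so for them reading past the end was not excluded. Shared control of neighbouring genes stays open as an untested hypothesis, and reads assigned to a wrong neighbour in a joint span were not excluded.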
